A study of Caenorhabditis elegans with 12 samples.

How the data were processed

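Chromatin of N2 larvae at the L3 stage, grown at 25 °C in liquid culture on HB101 *Escherichia coli* and collected 24 to 26 h after feeding, was crosslinked in 1% formaldehyde for 10 min and sonicated, per the labels' protocols. Per the same protocols, immunoprecipitation used a monoclonal antibody to ELT-2, an antibody to H3K4me3, or IgG alone as a mock control. Per those protocols, libraries were sequenced from a single end on Illumina HiSeq instruments for 50 cycles. The group and replicate number of each of the 12 libraries were taken from the labels, and the 2 RNA-seq libraries, whose labels carry no number, were numbered in order. The labels use the same replicate numbers across antibodies, but the H3K4me3 and the IgG ChIP each lack a library for 1 of these numbers.

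The authors deposited, for ELT-2 and for H3K4me3, a list of peaks and a list of their summits, each with the peak caller's score. The submitters' processing notes name Bowtie 1.1.0, MACS2 2.0.9 and bedtools for the ChIP libraries, TopHat2 2.0.14 and bedtools for RNA-seq, and the build ce10, with no order or settings. How the replicates of an antibody were combined into 1 list, and which control entered peak calling, are not given in the sources used here. The names of the deposited lists carry tags that read as removal of IgG peaks, blacklisted regions and HOT (high-occupancy target) regions, with a score over 30. In the lists themselves each score was above 30, the peak and summit lists held the same peaks with equal scores, and each summit lay within its peak. The other tags could not be tested on the lists. If such regions were removed, a site without a peak is not shown to be unbound, and overlap between antibodies at HOT promoters would be missing. The scale of the deposited score (a log of p or of q, with or without a factor) is not given in the sources used here, so scores were only ranked and compared within a list. The ELT-2, H3K4me3, IgG, input and RNA-seq libraries were not analysed here at the level of reads, and read depth per library is therefore unknown.

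Peaks were read with pandas 2.3.3 and analysed with numpy 2.4.6 and scipy 1.17.1 under Python 3.11.15. Figures were drawn with matplotlib 3.10.9. Overlap meant at least 1 shared bp. The span of a chromosome ran from the first to the last peak end in either list, since chromosome lengths of ce10 were not used here. For overlap, grouping and summit distance, each ELT-2 peak was placed 100000 times at random on its own chromosome within the span, with its width kept. Placed peaks could overlap one another, and placement did not follow gene density or mappability. Two-sided p-values of the placement tests and of the permutation tests of differences were double the smaller tail, so the smallest possible was 2e-05. Correlations were tested by 100000 permutations of the pairing. Their p-value was the share with an absolute value at or above the observed one, so the smallest possible was 1e-05. Shares between lists were compared by two-sided Fisher's exact tests. Scores and log2 widths were compared by two-sided permutation tests of the difference of medians with 100000 resamples, and their 95% intervals came from 10000 bootstrap resamples. Shares have 95% Wilson intervals and densities have exact Poisson intervals. Both treat peaks as independent and cover counting error only. The 7 main tests were adjusted together by the Benjamini-Hochberg method, and the distance intervals among themselves. All other p-values are unadjusted.

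The tests, the alternatives and the rule for naming sites were fixed before the data were examined, except where stated. The rule named the 15 highest-scoring ELT-2 peaks, the 10 highest H3K4me3 peaks and the 10 highest ELT-2 peaks that overlapped a H3K4me3 peak. Groups of 3 or more ELT-2 peaks and the fullest 1 Mb windows were chosen after their values were seen. So were the distance of 100 bp for coinciding summits, the distance intervals, the use of the running numbers in the peak names and the 1 Mb used for crowding of high scores. The comparison of paired widths was added after the data were examined and before its own result was seen. Alternatives were a stricter score (above the median of each list), other overlap and grouping distances, local shifts of 5 to 50 kb, counting peaks within 5000 bp once, another division of the arms and leaving out single chromosomes. The gene annotation at hand was of the WBcel235 build, and coordinates of different builds were not mixed. Promoter shares, fixed gene lists for the intestine and other tissues, and the GATA motif at summits had been planned for a ce10 reference and were therefore not analysed here. For the same reason no gene is named.

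The placement and permutation routines were tested on simulated data with the real 624 peak widths and scores. In 100 lists placed at random, the overlap test gave p under 0.05 in 2, the grouping test in 3 and the distance test in 6. In 100 random splits the score test did so in 4. The placed lists came from the same random placement as the tests use, with no added grouping. They check the routines, not how well random placement suits the real peaks. With 60 peaks moved onto H3K4me3 summits, the recovered excess was 63.9 overlaps.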

Results

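The data comprised chromatin immunoprecipitation sequencing (ChIP-seq) peak lists from L3 larvae of the wild-type *Caenorhabditis elegans* strain N2. ELT-2 is a GATA-type zinc finger transcription factor of the worm intestine. H3K4me3, trimethylation of lysine on histone H3, marks promoters of transcribed genes. The series holds 12 libraries in 5 groups. They are 3 ELT-2 ChIP, 2 H3K4me3 ChIP, 2 mock IgG ChIP, 3 input DNA and 2 RNA-seq libraries. The values used here are 1 peak list for each of the ELT-2 and H3K4me3 antibodies, with a position, a summit and the authors' peak score for every peak. No value belongs to a single library, so the spread between replicates could not be measured and every error below covers counting or placement error only. Read depth per library is unknown here. All coordinates are in the ce10 build and count from 1. Gene annotation of that build was not used here, so sites are named by position.

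The ELT-2 list held 624 peaks and the H3K4me3 list held 1562. ELT-2 peaks were narrow, with a median width of 343.5 bp (interquartile range 290.75 to 476.5), and together covered 271.1 kb. H3K4me3 peaks had a median width of 543.5 bp (interquartile range 385.25 to 823.0) and covered 1073.2 kb. The difference of median log2 widths was -0.66 (ELT-2 minus H3K4me3, 95% bootstrap interval -0.72 to -0.58). It passed a two-sided permutation test at p = 2e-05, the smallest value that test can give, and at an adjusted p of 3.5e-05 over the 7 main tests. Median peak scores were 43.8 for ELT-2 (range 30.04 to 462.26) and 57.0 for H3K4me3 (range 30.01 to 680.88). The scores are the caller's own and are ranked only within a list.

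The strongest ELT-2 sites lay mainly on chromosomes IV, II and V. Of the 15 peaks with the highest scores, 5 were on IV, 4 on II, 3 on V, 2 on X and 1 on III. Of the whole ELT-2 list, IV held 15.4%, II 20.0%, V 21.2%, X 25.5% and III 7.05%. The highest score, 462.26, belonged to a 408 bp peak on chromosome IV from 13919185 to 13919592. Another site on IV, from 3988628 to 3989036, scored 397.39, and that from 3899832 to 3900511 scored 344.76. The highest peak on V ran from 8768444 to 8768849 with a score of 341.34. The highest on X ran from 6606914 to 6607370 with a score of 336.67. On II, the peak from 1103700 to 1104075 scored 260.11 and that from 1851770 to 1852101 scored 252.49. On III, the peak from 2507962 to 2508301 scored 199.66. Among these 15 sites, 4 lay between 3.16 and 3.99 Mb on chromosome IV. The 15 peaks were 332 to 762 bp wide, and 1 of them overlapped a H3K4me3 peak.

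The 10 highest H3K4me3 peaks comprised 5 on chromosome IV, 4 on III and 1 on I, with widths from 913 to 2944 bp. Median scores followed another order, with 66.8 on X (14 peaks), 64.5 on III, 62.3 on I and the lowest median, 50.2, on IV. The highest score, 680.88, was at III from 13462201 to 13465144. The next were I from 10552863 to 10554642 with a score of 616.29, III from 12905000 to 12906327 with 603.26, and IV from 5946987 to 5947937 with 601.77. None of these 10 peaks overlapped an ELT-2 peak, but only 2.75% of all H3K4me3 peaks did. The nearest ELT-2 summit to the highest of the 10 was 80857 bp away.

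The lists were then compared by chromosome, since the H3K4me3 libraries came from matched worms, per the series description. Chromosome X held the largest share of the ELT-2 list and almost none of the H3K4me3 list. On X were 159 of 624 ELT-2 peaks (25.5%, 95% Wilson interval 22.2 to 29.0) against 14 of 1562 H3K4me3 peaks (0.896%, 0.535 to 1.50). The odds ratio was 37.7 (95% interval 21.6 to 71.3, two-sided Fisher's exact test p = 9.4e-76, adjusted p = 6.58e-75). Per Mb of span, ELT-2 had 9.19 peaks on X (exact Poisson interval 7.82 to 10.7) and 5.67 on the autosomes (5.17 to 6.21). H3K4me3 had 0.81 peaks per Mb on X (0.443 to 1.36) and 18.9 on the autosomes (17.96 to 19.9). These intervals and p-values treat peaks as independent, which neighbouring peaks are not. With peaks within 5000 bp counted once, the odds ratio was 28.2.

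Among the autosomes, ELT-2 peaks were densest on II, at 8.20 per Mb (6.83 to 9.77), and sparsest on III, at 3.20 per Mb (2.32 to 4.29). H3K4me3 peaks were densest on I and IV, at 24.3 (21.9 to 26.96) and 23.7 (21.5 to 26.2) per Mb, and sparsest on V, at 11.95 (10.5 to 13.5). Chromosome II had 15.7 H3K4me3 peaks per Mb (13.8 to 17.8). These orders hold for the listed peaks. The running numbers in the peak names, if they count a longer list, gave V the highest density among the autosomes for both antibodies. For ELT-2 they gave 172.7 per Mb on V and 102.4 on II, where 8.01% of the numbers were in the list against 3.56% to 4.23% on the other autosomes. For H3K4me3 they gave 233.5 per Mb on V and 226.6 on I, with 5.12% and 10.7% in the list.

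**Figure D1:**
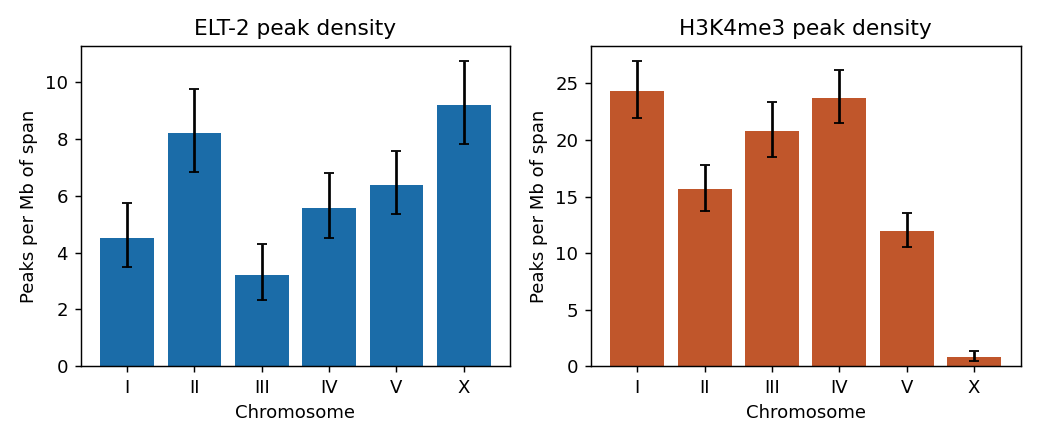
ELT-2 (left) and H3K4me3 (right) peaks per Mb of chromosome span, by chromosome, with exact 95% Poisson intervals as error bars. ELT-2 reaches 9.19 peaks per Mb on X, where H3K4me3 has 0.81.

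For position along the autosomes, each chromosome span was divided into 3 equal parts and the outer parts were compared with the middle part, because worm autosomes have gene-dense centres and repeat-rich arms. The outer parts held 329 of 465 autosomal ELT-2 peaks (70.8%) and 1032 of 1548 H3K4me3 peaks (66.7%). An even spread along the spans would also put 66.7% of peaks in the outer parts. The odds ratio of 1.21 (95% interval 0.960 to 1.53) did not pass the threshold (two-sided Fisher's exact test p = 0.102, adjusted p = 0.118). On IV, 256 of 410 H3K4me3 peaks lay in the left part (62.4%), beside 38 of 96 ELT-2 peaks (39.6%), a difference that was not tested by itself. The 4 fullest 1 Mb windows of H3K4me3 were the first 4 of chromosome IV, with 54, 60, 48 and 51 peaks, where the median window held 14. Median scores in these windows were 45.85, 43.1, 43.29 and 49.12, below the list median of 57.0. The densest ELT-2 windows were from 3 to 4 Mb on II, with 17 peaks, and on IV, with 16, where the median window held 5. Median scores were 35.14 in the window on II and 48.24 in that on IV, beside 43.8 for the ELT-2 list. The arm comparison passed the threshold without chromosome IV (odds ratio 1.41, Fisher's exact test p = 0.00728) and with peaks within 5000 bp counted once (1.38, p = 0.00962). Its direction turned among peaks with scores above the median of their list (0.952, Fisher's exact test p = 0.752). Over the running numbers in the peak names, of which a smaller share was listed in the outer parts than in the middle part, the odds ratio was 1.62 (Fisher's exact test p = 3.72e-52, with numbers treated as independent).

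**Figure D2:**
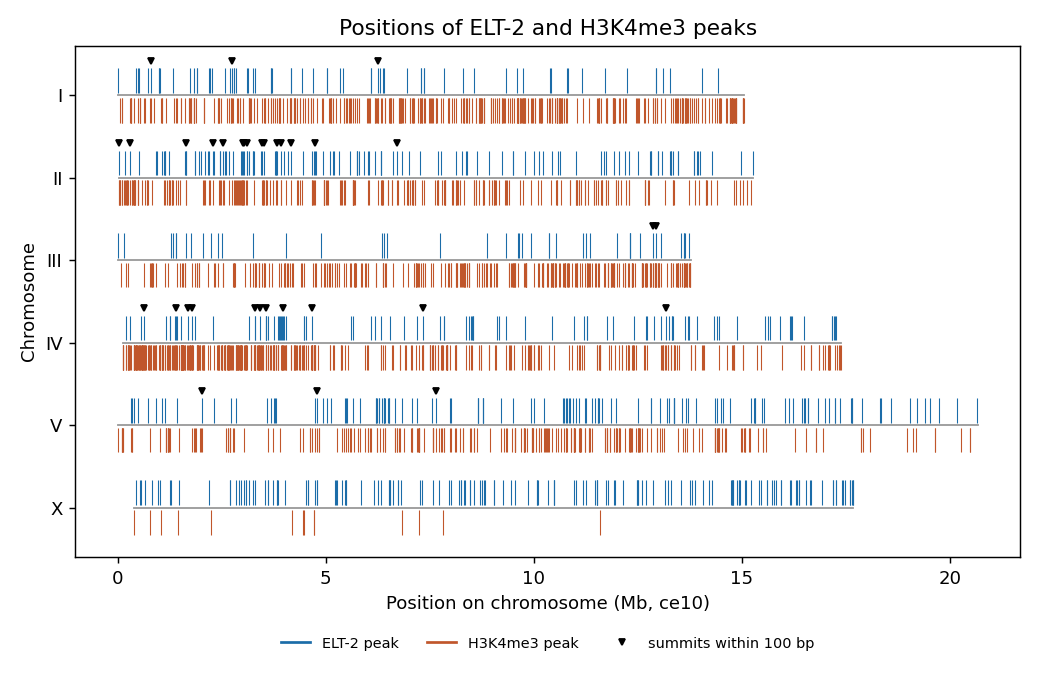
Positions in Mb (ce10) of ELT-2 peaks (blue, above each line) and H3K4me3 peaks (orange, below) on the 6 chromosomes; triangles mark the 34 ELT-2 peaks whose summit lies within 100 bp of a H3K4me3 summit. Of these triangles 15 are on chromosome II and 11 on IV, and X carries none.

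Overlap between the lists addressed how often a listed ELT-2 peak met a listed H3K4me3 peak in the same larval stage. It does not measure direct binding at promoters, since the GATA motif was not analysed and HOT regions appear to have been removed. The lists do not tell tissues apart. Few ELT-2 peaks overlapped a H3K4me3 peak: 43 of 624 did so by at least 1 bp (6.89%, 95% Wilson interval 5.16 to 9.15). Random placement of the ELT-2 peaks on their own chromosomes gave a mean of 9.02 overlaps (95% range 4 to 15), so the observed number was 4.77 times the expected one. None of the 100000 placements reached it (two-sided permutation p = 2e-05, the smallest possible, adjusted p = 3.5e-05). Chromosome II held 17 of the 43 overlaps and IV held 14, against 5 on I, 4 on V and 3 on III. The ratio to placement was 2.91 when a gap of up to 500 bp counted as overlap, and 7.25 when the ELT-2 summit had to lie within the H3K4me3 peak. On X, 0 of 159 ELT-2 peaks overlapped, and only 14 H3K4me3 peaks were there to be met. An approximate one-sided 95% upper bound on that share, taken as 3 of 159 and not as a Wilson bound, was 1.89%.

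At most overlaps the summits of both lists lay close together. In 34 of the 43 pairs the summits lay less than 100 bp apart (79.1%, Wilson interval 64.8 to 88.6), with a median distance of 20 bp. At those 34 sites the median widths were 369 bp for ELT-2 and 431.5 bp for H3K4me3, and the widths rose together across sites (Spearman's rho 0.962, Pearson's r of log2 widths 0.9497, permutation p = 1e-05 for each, the smallest possible). Without the 2 sites farthest from the median ELT-2 width, rho was 0.956 and r was 0.940. These correlations run across sites, which are not independent replicates. The start and the end of the paired peaks differed by medians of 23.5 and 29.5 bp. Overlaps with summits at least 100 bp apart numbered 9, where random placement gave a mean of 7.33 (95% range 3 to 13, permutation p = 0.624), so the excess over random placement was not detectable without the coinciding sites. The 100 bp limit was chosen after the values were seen, so leaving these sites out was bound to lower the excess.

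Most of the 43 overlapping ELT-2 peaks scored below the median of their list, and 10 scored above it. The highest-scoring overlapping ELT-2 peak, on IV from 3611595 to 3612311, scored 282.56 and had its summit 1007 bp from the nearest H3K4me3 summit. The second, on I from 1836147 to 1836491, scored 151.84 at 427 bp, and the third, on III from 13605581 to 13606422, scored 90.39 at 450 bp. The next 7 of the 10 highest scored between 44.58 and 65.0, and each had its summit within 52 bp of a H3K4me3 summit. In this group were V from 4784567 to 4784796 with a score of 65.0 and IV from 3568255 to 3569007 with 64.91. These 10 were 3.21% of the 312 ELT-2 peaks above the median, where random placement against all H3K4me3 peaks gave a mean of 4.57 (permutation p = 0.0364, a test added after the data were examined). With the H3K4me3 list also limited to scores above its median, 4 of the 312 overlapped (1.28%), where placement gave a mean of 2.47 (permutation p = 0.475).

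**Figure D3:**
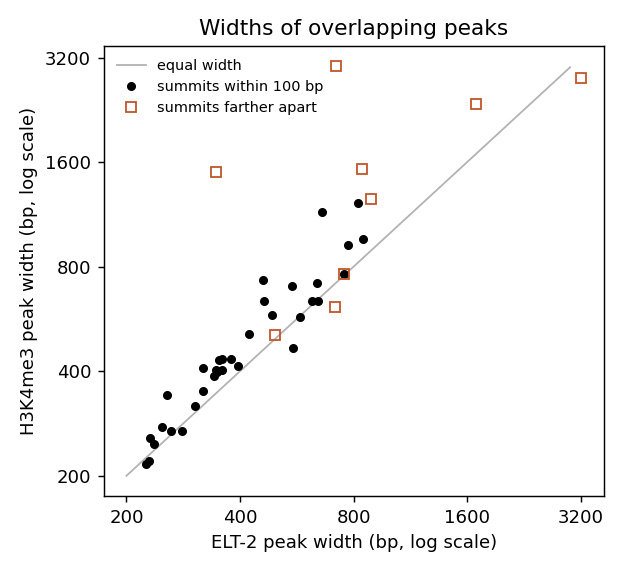
Width in bp of each overlapping H3K4me3 peak against that of its ELT-2 peak, both on log scales, for the 34 pairs with summits within 100 bp (filled circles) and the 9 pairs with summits farther apart (open squares); the line marks equal widths. The 34 coinciding pairs rise along the line and lie mostly above it, with medians of 369 bp for ELT-2 and 431.5 bp for H3K4me3 and the ELT-2 peak at least as wide in 6.

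Among the listed peaks, those that overlapped had lower scores in both lists. Overlaps at HOT promoters, if removed as the list names read, are not in this comparison. The median ELT-2 score was 36.55 in the 43 peaks that overlapped and 44.55 in the 581 that did not, a difference of -8 (95% bootstrap interval -11.7 to -4.12, two-sided permutation p = 0.00214, adjusted p = 0.0030). The median H3K4me3 score was 39.3 in the 43 overlapping peaks and 58.15 in the 1519 others, a difference of -18.85 (interval -23.7 to -11.7, permutation p = 6.4e-04, a test added after the data were examined). Without chromosome II the ELT-2 difference was -6.37 and the permutation p was 0.0859.

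ELT-2 summits lay close to H3K4me3 summits at the coinciding sites, and at the other distances tested no excess over random placement was detected. The median distance from an ELT-2 summit to the nearest H3K4me3 summit was 38284 bp, against a median of 40740 bp over placements (95% range 35427.5 to 46837.5, permutation p = 0.387, unadjusted and adjusted). The distance itself depended on the peaks used. It was 21850 bp without chromosome X (placements 24612 bp, permutation p = 0.114). Among peaks with scores above the median of their list it was 72553 bp (placements 73615.5 bp, permutation p = 0.875). By distance, 34 ELT-2 summits lay under 100 bp from a H3K4me3 summit where 1.70 were expected, a ratio of 20.0 (permutation p = 2e-05, adjusted p = 1e-04 over 10 tests, which are 5 intervals under whole-chromosome placement and under local shifts). Between 100 and 1000 bp there were 15 where 14.1 were expected (permutation p = 0.882, adjusted p = 1). Between 1000 and 5000 bp there were 54 where 53.4 were expected (permutation p = 0.975, adjusted p = 1). Between 5000 and 20000 bp there were 117 where 138.7 were expected (permutation p = 0.03004, adjusted p = 0.0751). Local shifts of 5 to 50 kb gave 148.1 for that interval (permutation p = 4.8e-04, adjusted p = 0.0016), so the call changed with the placement. Such shifts carry the 34 coinciding peaks 5 to 50 kb away from their H3K4me3 summits, and without those peaks the mean was 130.2 (permutation p = 0.139, adjusted p = 0.657), in a test added after the data were examined.

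**Figure D4:**
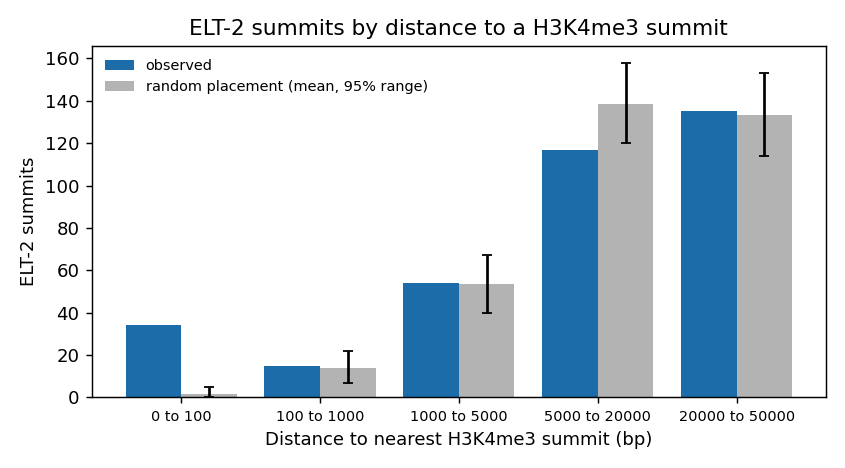
Number of ELT-2 summits by distance in bp to the nearest H3K4me3 summit (blue), beside the mean and 95% range of 100000 random placements (grey). Under 100 bp the list had 34 summits against 1.70 expected, and from 100 to 1000 bp it had 15 against 14.1.

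ELT-2 sites occurred in groups more often than random placement gave. Of 624 summits, 124 had another ELT-2 summit within 5000 bp (19.9%, Wilson interval 16.9 to 23.2), where placement gave a mean of 41.3 (95% range 26 to 59), a ratio of 3.00 (permutation p = 2e-05, the smallest possible, adjusted p = 3.5e-05). These peaks formed 59 groups: 54 pairs, 4 groups of 3 and 1 group of 4. Chromosome X held 20 of the groups, II and V held 12 each, IV held 8, I held 5 and III held 2. The group of 4 spanned 8714 bp on V, from 13372622 to 13381335, with scores from 34.32 to 96.35. The groups of 3 were on II from 5748437 to 5751697, IV from 8527431 to 8531009, V from 6407571 to 6413486 and X from 10477115 to 10480925, and the last contained a peak with a score of 170.69. When each peak was instead shifted by 5 to 50 kb from its own position, the mean number was 55.0 and the ratio was 2.26 (permutation p = 2e-05). Among peaks with scores above the median the ratio was 4.62.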

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

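The tests in this part were chosen after the results were seen. The names of the peaks carry running numbers, which are not among the measured values of the lists, and these reach 13804 in the ELT-2 list and 16058 in the H3K4me3 list. The numbers rise along each chromosome and from chromosome to chromosome, as they would in a longer list from which the 624 and 1562 peaks were drawn. On that reading at most 4.52% of numbered ELT-2 peaks and 9.73% of numbered H3K4me3 peaks were kept.

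The kept share differed between regions. On chromosome V it was 5.12% of 4825 H3K4me3 numbers, against 11.9% of 10944 on I to IV (odds ratio 0.3999, 95% interval 0.346 to 0.461, two-sided Fisher's exact test p = 8.85e-44). For ELT-2 it was 3.70% on V against 4.85% on I to IV (odds ratio 0.754, Fisher's exact test p = 0.00688). Without chromosome II in the comparison, the share on V was set against 3.92% for ELT-2 (Fisher's exact test p = 0.612) and 11.8% for H3K4me3 (Fisher's exact test p = 1.46e-40), so the ELT-2 call rested on II. On II itself the kept share was above that of the other autosomes in both lists, at 8.01% against 3.83% for ELT-2 (odds ratio 2.19, Fisher's exact test p = 9.42e-12) and 12.4% against 9.46% for H3K4me3 (odds ratio 1.35, Fisher's exact test p = 1.03e-04). In the outer parts of the autosomes it was 3.91% for ELT-2 and 8.93% for H3K4me3, against 7.74% and 13.2% in the middle part (odds ratios 0.485 and 0.643, Fisher's exact test p = 5.98e-11 and 5.43e-14). With the numbers in place of listed peaks, the outer parts held 82.7% of ELT-2 and 74.8% of H3K4me3 numbers. The odds ratio was then 1.62, and between 1.24 and 1.86 for any place of the 465 and 359 numbers that fall between parts, against 1.21 for the listed peaks.

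H3K4me3 peaks were scarce on chromosome X, and filters applied after calling may have removed them, but left of the last kept X peak, at 11.6 Mb, at most 236 numbers fell on X, or 20.3 per Mb against 193.0 on the autosomes. This argues against the filters as the whole cause there, since the numbers themselves were scarce. Over the remaining 6.07 Mb of X no number is seen, so removal by filters cannot be told apart from a lack of calls there. Poor mapping of X, or few reads from it in every library, is argued against by the 25.5% of ELT-2 peaks that lay on X, above its 17.4% of the spans. Low H3K4me3 signal on X in these larvae, or a step special to the H3K4me3 libraries, stays open, and no biological explanation was tested.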

How the results depend on the processing

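Over 7 results, 47 alternatives were run, of which 24, chosen after the data were examined, left out single autosomes, used local shifts for grouping, set aside coinciding summits, counted all peak numbers or limited the ELT-2 list alone by score. In 40 the direction and the side of the threshold stayed as reported. Among peaks with scores above the median of their list, the overlap share was 1.28% and no longer passed, and the arm odds ratio turned to 0.952. This alternative tests fewer peaks of both lists. With the ELT-2 list alone limited in this way, the overlap share was 3.21% and passed. Restricting overlaps to summits at least 100 bp apart gave 1.44%, no longer past the threshold, because it removes the coinciding sites. The arm odds ratio passed at 1.38 with peaks within 5000 bp counted once, at 1.41 without chromosome IV and at 1.62 over all peak numbers, where the share listed was lower in the arms. The score difference without chromosome II was -6.37 and did not pass. The cause of these changes was not tested. The X share, the widths, the grouping and the summit distance kept their call in each alternative run for them, with odds ratios of 28.2 to 36.1 for the X share, log2 width differences of -0.84 and -0.71 and grouping ratios of 2.02 to 4.62. Another 12 alternatives, for promoters, gene lists and the GATA motif, were not run for want of a reference in ce10. No paired analysis was possible because each antibody has 1 list and no value per replicate, and for the same reason no replicate could be left out. Read depth, unknown here, limits which weak sites could be called.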

Other observations

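All tests in this part were chosen after the data were examined, those of paired widths and of local shifts before their own results were seen. ELT-2 peaks were wider on chromosome X than on the autosomes. Their median width was 412 bp on X and 333 bp on the autosomes, a log2 difference of 0.31 (95% bootstrap interval 0.15 to 0.46, two-sided permutation p = 2e-05, the smallest possible), while median scores were 43.02 and 43.9 (permutation p = 0.658). X held 137 of 556 ELT-2 regions when peaks within 5000 bp were counted once, more than its 17.4% of the spans (exact binomial p = 1.98e-05). The running numbers of the ELT-2 list gave 179.1 per Mb on X, 129.8 on the autosomes and 172.7 on V. Of these numbers 5.15% were listed on X, against 3.56% to 8.01% on single autosomes, so the X excess among listed peaks may depend in part on the filters. The 14 H3K4me3 peaks on X were unevenly spread, with 10 in the left of 3 equal parts, 4 in the middle and 0 in the right (exact multinomial p = 0.00196). Of the 15 highest-scoring ELT-2 peaks, 4 lay within 1 Mb on chromosome IV. In 100000 shuffles of the scores over the ELT-2 peaks, the fullest 1 Mb held a mean of 2.09 (one-sided permutation p = 0.0100). The 1 Mb was chosen after these positions were seen, so the p-value is not independent support.

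Most overlaps between ELT-2 and H3K4me3 peaks had coinciding summits. Overlapping short peaks have close summits by chance, but sliding each ELT-2 peak over its partner put 21.7% of pairs within 100 bp (95% range 9.30 to 34.9), against 79.1% observed. A candidate explanation is signal common to both immunoprecipitations at the same spot, which predicts paired widths, and widths rose together with a rho of 0.962 (bootstrap interval 0.891 to 0.982). Joint occupancy of small sites could give paired widths too, so rho does not separate these explanations. The list names read as removal of IgG peaks, which could not be tested on the lists. The 34 coinciding ELT-2 peaks also had lower scores than the others (difference of medians -8.65, permutation p = 0.00156), and their H3K4me3 partners 39.1 against 58.1 (p = 0.0017), so that they sat near the score minimum of both lists, and 30 of them were in the outer parts of autosomes (88.2% against 69.4% of other autosomal ELT-2 peaks, Fisher's exact test p = 0.0187). True joint occupancy of small sites stays open, since IgG and input coverage at these 34 sites, which would separate the explanations, was not analysed here.

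Groups of ELT-2 peaks within 5000 bp may reflect uneven density at larger scale or wide sites split by the caller. Local shifts of 5 to 50 kb keep the larger-scale density, and none of 100000 had as many grouped peaks (one-sided permutation p = 1e-05, the smallest possible). Peaks whose nearest neighbour was 2000 to 5000 bp away numbered 58, where whole-chromosome placement gave a mean of 24.4 (95% range 12 to 38). That is too far for pieces of a typical peak, but the widest ELT-2 peak was 3213 bp. Neither density at a scale of 50 kb or more nor the splitting of sites of typical width accounts by itself for all of the grouping. Splitting of wider sites and uneven density at a smaller scale stay open. Several regulatory sites of 1 gene, or sites of neighbouring genes, stay open as a hypothesis that gene annotation in ce10 would test.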
